A study of Mus musculus with 9 samples.

How the data were processed

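The deposited table holds raw counts per gene, with an Ensembl identifier and a symbol for each of 54838 genes, in 9 columns, 1 for each of 3 overlap, 3 mCherry and 3 cfos libraries. Per the labels' protocols, RNA was released by lysis of laser-captured cells and made into Smart-3SEQ libraries, in which reads start near the 3′ end of a transcript and can carry molecular identifiers. Per the submitters' processing notes, Trim Galore, STAR, UMI-tools and featureCounts were used with the mm10 build. Their versions, the annotation, the strand setting and how the molecular identifiers were used are not given in the sources used here. Counts that used no identifiers would hold PCR copies, so intervals and floors cover counting error only. Values of 3′ libraries depend little on gene length, and cannot separate isoforms that share a 3′ end.

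Of the identifiers, 54809 matched the GENCODE M21 annotation of the same build, from which coordinates and gene types were taken. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart. This applies to Nefl with Nefm, Syngr1 with Rpl3, Syn2 with Timp4, Gnaz with Rsph14, Ndufa2 with Tmco6, Nrxn2 with Slc22a12, and to predicted-gene overlaps such as those of Pclo and Snap25. All 37 mitochondrially encoded genes were at 0 in every column, and so gave no measure of RNA quality. Predicted genes took 13.6% of the counts in cfos 1 and 19.9% to 27.0% in the other columns, and 1 predicted gene took 7.54% in overlap 1.

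A count of 0 in a library allows up to 3 counts, which is 5.02 to 5.94 CPM in overlap, 3.06 to 3.42 CPM in mCherry and 0.879 to 4.28 CPM in cfos. The overlap libraries were the shallowest. The columns cfos 2 and cfos 3, counted as 1 replicate, were the deepest, while cfos 1 had fewer counts than every mCherry library. Of the genes tested, 7.62% to 21.2% were at 0 in any one replicate.

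Columns were compared in pairs before any mean was taken. All genes of cfos 2 had counts at or below those of cfos 3, with a ratio of totals of 0.548 and a correlation of log2 CPM across genes of 0.995, against 0.342 to 0.815 in the other pairs. Their rounded mean was used as 1 replicate. The design fixed before the data were examined had all 9 columns as separate samples. The averaging was decided after the number of genes called with all 9 columns had been seen, and both sets of counts are therefore reported. The column mCherry 2 was not a copy of another column and stayed in. It exceeded the sum of mCherry 1 and mCherry 3 in 0 genes, while of the other 251 combinations of a column with the sum of 2 others, the 7 that set cfos 2 against cfos 3 and another column had 0 such genes and the remaining 244 had 2198 to 17675.

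The tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered by filterByExpr by group, which left 16410. Counts were scaled by TMM, 1 quasi-likelihood model with robust dispersion was fitted to all 3 groups without covariates (biological coefficient of variation 0.958), and the 3 contrasts were tested in either direction with Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of its F value. CPM are counts over TMM-scaled library sizes, and a prior count of 2 was used for log2 CPM. For a gene with 0 counts in a group, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts, the ratio is given with its exact binomial (Clopper-Pearson) 95% interval. Sums over mCherry include mCherry 2, whose reads may also be among those of mCherry 1 and mCherry 3. Intervals that involve mCherry may therefore be too narrow, and floors too high. Sums over cfos use the rounded mean of cfos 2 and cfos 3, which is not a count of reads, so intervals that involve cfos are approximate.

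A total of 30 gene lists was fixed before the data were examined: PVH peptides and identity genes, immediate early genes, markers of neurons, glia, vessels, ependyma, fibroblasts, blood and neighbouring nuclei, receptors and channels, synaptic genes, stress, inflammation, respiration, ribosomes, long RNAs and sex-linked genes. The 28 lists with at least 5 tested members (3 for 2 short lists) were tested by camera with a preset correlation of 0.01, and the erythrocyte and mitochondrially encoded lists had too few. No member of a called list was at 0 throughout a group, so that the medians of called lists hold no lower bounds. In 6, 7 and 5 lists of the 3 comparisons, none of them called, the median, the mean and the direction of the test differed in sign.

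The genes named were chosen by a rule fixed in advance. It takes the 8 genes of smallest p in each direction past the threshold and up to 12 further list genes. Where fewer than 10 pass, it takes the 5 of smallest p in each direction, stated as not past it. It always takes Fos, Crh, Avp, Oxt, Trh, Sst, Slc17a6, Gad2 and Slc32a1, and up to 4 members of smallest p from each called list as examples. Predicted genes were counted and not named, and some genes that the rule selects are not analysed here. Genes outside this rule are said to be so where they appear.

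The same code was tested on simulated counts with the means, dispersions and library sizes of the 8 replicates, as independent libraries, with 200 genes changed. At a true fold of 4, 0 of the changed genes were called in any comparison. At a true fold of 16, 10.9% were called in overlap versus mCherry (14908 genes), 6.67% in overlap versus cfos (14800 genes) and 15.5% in cfos versus mCherry (14924 genes), with 0 false calls. A list lowered by a fold of 2 was found each time, with 0 other lists called. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. In 20 simulations of 15274 genes with no group difference and the nesting of the real columns, the median share of genes at an unadjusted p under 0.05 was 10.9%, 7.44% and 10.7% in the same order for the 8 replicates, and 4.63%, 4.74% and 4.79% without mCherry 2. The real shares were 15%, 11.8% and 17.7%, and 6.44%, 8.33% and 9.31% without mCherry 2.

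Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no count filter, at least 10 counts in at least 6 replicates, the replicate number as a block, removal of mitochondrial and ribosomal protein genes, each library left out, fits of only the groups compared, an estimated correlation in camera, and fry. Alternatives added after seeing the data were all 9 columns, the block with all 9 columns, neither cfos 2 nor cfos 3, and DESeq2, limma-voom or no filter with mCherry 2 left out, and the immediate early list without Fos. All columns of the table were used.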

Results

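Mouse brain cells were cut out by laser-capture microdissection, which collects chosen cells from a tissue section under a microscope, and were sequenced as Smart-3SEQ libraries, which read the 3′ ends of polyadenylated RNA. The series concerns the paraventricular hypothalamus (PVH), a nucleus of neuroendocrine and autonomic neurons, in visceral and somatic pain. The labels name 3 groups of 3 libraries each, called mCherry (a red fluorescent protein), cfos (the protein of the immediate early gene Fos) and overlap. The design text speaks of cells labelled by CRD, by VFF or by both. The labels do not say which of mCherry and cfos stands for CRD and which for VFF, so the groups keep their label names here. The labels call the libraries biological replicates and name no animals, so the p-values measure the spread between these libraries. The total counts were 597898, 545568 and 504785 in the overlap libraries, 962676, 877257 and 978877 in the mCherry libraries, and 700556, 1871820 and 3414593 in the cfos libraries.

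The columns were not all separate samplings of RNA. The count of cfos 2 was at or below that of cfos 3 in every one of the 54838 genes, and these columns differed by less than the sampling noise (chi-square per gene 0.844, against 9.24 to 67.9 in the other 35 pairs of columns). They were therefore averaged and counted as 1 sample, which leaves 3 overlap, 3 mCherry and 2 cfos replicates. The count of mCherry 2 was at or below the sum of mCherry 1 and mCherry 3 in every gene as well. The column mCherry 2 differed from both by more than sampling noise and was kept, so mCherry n = 3 includes a library that is not independent. The p-values of all 3 comparisons are too small for that reason, since they share the estimated spread. In simulations without group differences 10.9%, 7.44% and 10.7% of genes were under 0.05, against 4.63%, 4.74% and 4.79% without mCherry 2. The simulated mCherry 2 was drawn as fixed shares of mCherry 1 and mCherry 3, unlike the real column, so the size of the real excess is not known. Without cfos 1, or with neither cfos 2 nor cfos 3, cfos has 1 replicate, which is then assumed to vary like the other groups, so that passing or failing there rests on their spread. Each comparison therefore also gives its counts without mCherry 2 and with all 9 columns. The averaging, and the counts by DESeq2, by limma-voom and without a filter when mCherry 2 was left out, were chosen only after results had been seen.

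Fos itself is a limited check on the labels, since its protein names one of them, and is no finding between the groups. The counts measure Fos RNA, so low values do not show that cells lacked the protein. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, protein-coding) was at 71.5, 206 and 279 CPM (counts scaled to the effective library size) in the overlap libraries and at 30.6, 21.0 and 11.1 CPM in the mCherry libraries. The library labelled cfos 1 had 283 CPM, while those labelled cfos 2 and cfos 3 had 23.8 and 25.5 CPM, within the mCherry range. Every direction below that involves the cfos group therefore rests on 1 library with high Fos and 1 averaged pair with low Fos.

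**Figure D1:**
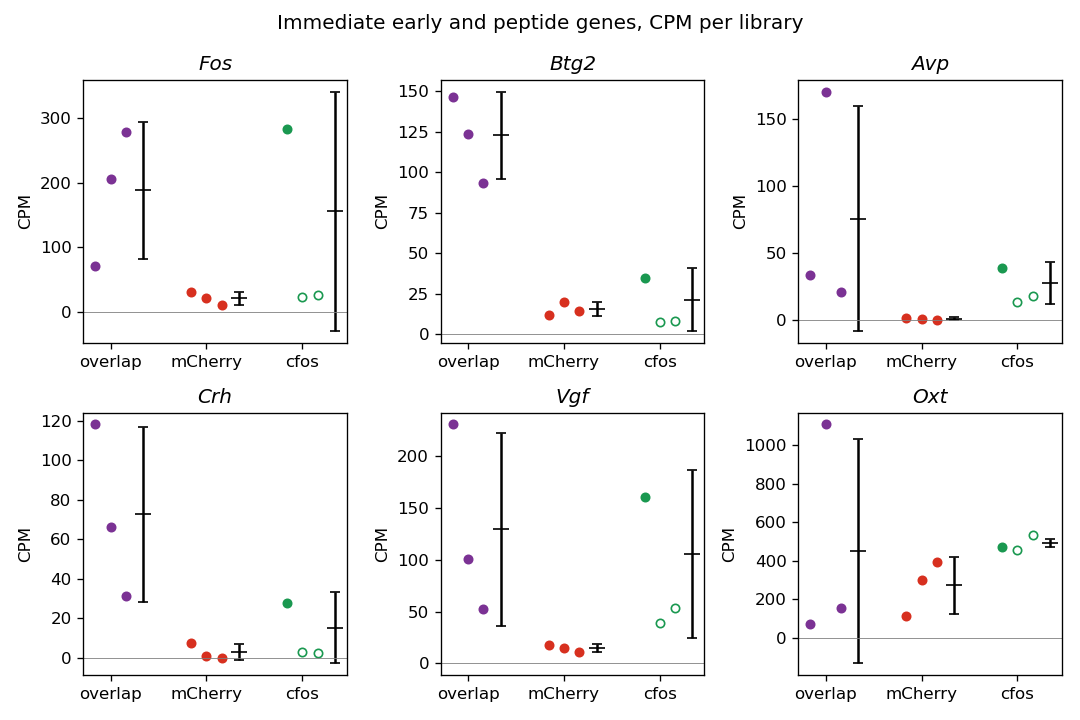
CPM (linear axis) of the immediate early genes Fos and Btg2 and the peptide genes Avp, Crh, Vgf and Oxt in each library. Points are libraries (open points are cfos 2 and cfos 3, averaged as 1 replicate) and bars are the mean ± SD over 3 overlap, 3 mCherry and 2 cfos replicates; Btg2 lies between 93.7 and 147 CPM in the overlap libraries and between 11.6 and 19.8 CPM in the mCherry libraries.

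Overlap was compared with mCherry to ask how cells with both labels differed from cells with the mCherry label. Genes of synaptic vesicle release, which dock, prime and fuse transmitter vesicles, were lower as a group in overlap, with a median log2 fold change of -0.69 and 23 of 32 measured members below 0. Pan-neuronal genes, expressed by nearly all neurons, were lower as a group, with a median of -0.42 and 20 of 24 members below 0. Immediate early genes, transcribed soon after neuronal activity, were higher as a group, with a median of 1.83 and 16 of 21 members above 0. Since overlap cells also carry the cfos label, the choice of cells may by itself favour this list. None of these 3 calls held with an estimated correlation (adjusted p = 0.612 each). The peptide genes Avp (vasopressin) and Crh (corticotropin-releasing hormone) stood at 75.9 ± 83.8 and 72.7 ± 44.2 CPM in overlap (SD, n = 3) and at 1.1 ± 1.07 and 2.88 ± 4.01 CPM in mCherry (SD, n = 3), but neither passed the test over all genes.

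Among the vesicle genes, the calcium sensor Syt1 had a log2 fold change of -1.62 (SE 0.42), Sncb (beta-synuclein) -1.55 (SE 0.50), Syngr1 (synaptogyrin) -1.99 (SE 0.68) and the active-zone scaffold Pclo -0.82 (SE 0.31). Among the pan-neuronal genes, Map1b, a microtubule-associated protein, had -1.28 (SE 0.35), Nefl, a neurofilament subunit, -1.03 (SE 0.46) and the SNARE protein gene Snap25 -1.12 (SE 0.53). Syt1 and Snap25 belong to both lists. Of the immediate early genes, Btg2 had a log2 fold change of 2.99 (SE 0.87), the peptide-processing enzyme Pcsk1 3.78 (SE 1.31) and the transcription factor Klf6 2.21 (SE 0.83). Adjusted over the list alone, 0 members of these 3 lists passed, and 0 passed over all genes. The camera test of each list against the other genes gave adjusted p = 0.0286 for vesicle release, 0.033 for pan-neuronal genes and 0.033 for immediate early genes. With an estimated correlation the adjusted p = 0.612 for each, and without Fos the immediate early list did not pass (adjusted p = 0.085), nor with a stricter count filter (median 0.44, adjusted p = 0.268). Fry, a rotation test of whether the genes of a list move on balance one way, called 0 lists. Glial markers had medians of similar size below 0 and did not pass: astrocyte markers -0.38 with 13 of 16 members below 0 (camera adjusted p = 0.424) and oligodendrocyte markers -0.40 with 8 of 11 (0.353).

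The 3 calls depended on single libraries. The immediate early list passed with none of the 6 libraries left out in turn (adjusted p = 0.0704, 0.12 and 0.0515 without overlap 1, 2 and 3, and 0.146, 0.0663 and 0.11 without mCherry 1, 2 and 3). The vesicle list did not pass without overlap 1 (0.258), mCherry 1 (0.0716) or mCherry 3 (0.0864), and the pan-neuronal list did not pass without overlap 1 (0.311), overlap 3 (0.161), mCherry 1 (0.146) or mCherry 3 (0.0864). The immediate early median was 1.04 without overlap 2 and the vesicle median -0.43 without overlap 1, while the pan-neuronal median lay between -0.48 and -0.34 in the omissions that ended its call. Without mCherry 2 both of these neuronal lists passed (0.00229 and 0.00326). The number of called lists was 2 without mCherry 2, 2 with all 9 columns, 0 without overlap 1, without mCherry 1 or without mCherry 3, and 1 without overlap 3.

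The list of PVH neuropeptides and secretory granule proteins had 9 of 12 members above 0 and a median log2 fold change of 1.17, and did not pass (camera adjusted p = 0.218). Adjusted over the list alone, 2 members passed, Avp and the granule protein gene Vgf, and over all genes 0. Avp (ENSMUSG00000037727, chromosome 2, 130580620 to 130582554, protein-coding) had 124 counts over the overlap libraries and 3 over the mCherry libraries, a ratio of 72.3 with a 95% counting interval from 24.2 to 355. Its counts were 19, 95 and 10 in overlap 1, 2 and 3, so most came from overlap 2. They were 2, 1 and 0 in mCherry 1, 2 and 3. Its adjusted p was 0.258 over all genes, with a range of 0.00191 to 0.864 over the alternatives. Crh (ENSMUSG00000049796, chromosome 3, 19693401 to 19695396, protein-coding) had a log2 fold change of 4.59 (SE 1.58, adjusted p = 0.275). Oxt (oxytocin) had 0.73 (SE 0.87), and its sign turned to -1.25 without overlap 2, which held 1108 CPM against 69.8 and 154 in the other overlap libraries. Trh (1.60, SE 1.09), Sst (0.41, SE 1.74), the glutamate transporter gene Slc17a6 (-0.64, SE 0.78) and the GABA-synthesising enzyme gene Gad2 (0.87, SE 0.84) did not pass either. Slc32a1, the vesicular GABA transporter gene, fell below the count filter, with 1, 0 and 0 counts in overlap and 12, 4 and 0 in mCherry.

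No single gene passed: edgeR's quasi-likelihood test called 0 of 16410 genes, with 2457 at an unadjusted p under 0.05. DESeq2 called 905 genes, limma-voom with sample weights 1332 and edgeR without a count filter 484. Without mCherry 2, edgeR called 0 of 15274 genes (983 at an unadjusted p under 0.05), DESeq2 141, limma-voom 0 and edgeR without a filter 13, and with all 9 columns edgeR called 0. The 5 higher and 5 lower genes with the smallest p, none past the threshold (adjusted p = 0.258 each), were as follows. Dapk2, a death-associated protein kinase gene (ENSMUSG00000032380, chromosome 9, 66158223 to 66272242, protein-coding), had 0 counts in mCherry and was at least 73.5-fold higher in overlap, and Armh3 was at least 42.6-fold higher, both against a floor of 3 counts over the group. Rmdn1 and Colec12 had 2 counts each over the mCherry libraries, with ratios of 175 (95% counting interval 47.8 to 1455) and 136 (36.9 to 1130), and Dpysl4 had a log2 fold change of 4.88 (SE 0.87). In mCherry 1, 2 and 3 the counts were 0, 1 and 1 for Rmdn1 and 1, 1 and 0 for Colec12. With mCherry 2 nested, the 2 counts may be 1 read. Intervals and floors against mCherry, here and in cfos versus mCherry, may be too narrow or too high for that reason. In the other direction, the adhesion gene Ntm had -1.99 (SE 0.33), the protease gene Bmp1 -1.87 (SE 0.32) and Fam160b2 -3.47 (SE 0.75). Ebi3, a cytokine subunit gene, had 0 counts in overlap and was at least 81.1-fold lower there, and Zbtb2 had 1 count in overlap, with an mCherry to overlap ratio of 189 (33.6 to 7470). The other 25 lists had adjusted p between 0.218 and 0.889.

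Overlap was compared with cfos to ask how cells with both labels differed from cells with the cfos label. Neuronal and metabolic gene groups were lower in overlap: 11 of 28 lists passed, all in that direction. None of the 11 held with an estimated correlation (adjusted p = 0.097 to 0.269). Synaptic vesicle release had a median log2 fold change of -1.13 with 29 of 32 members below 0, pan-neuronal genes -0.997 with 21 of 24, and nuclear-encoded oxidative phosphorylation, the respiratory chain of the mitochondrion, -1.17 with 38 of 50. Oligodendrocyte markers, genes of the myelin-forming glia, were lower as a group as well, with a median of -1.65 and 10 of 11 below 0, and so were astrocyte markers, with -0.61 and 9 of 16. All 9 nuclear-retained long RNAs were below 0, with a median of -1.11.

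**Figure D2:**
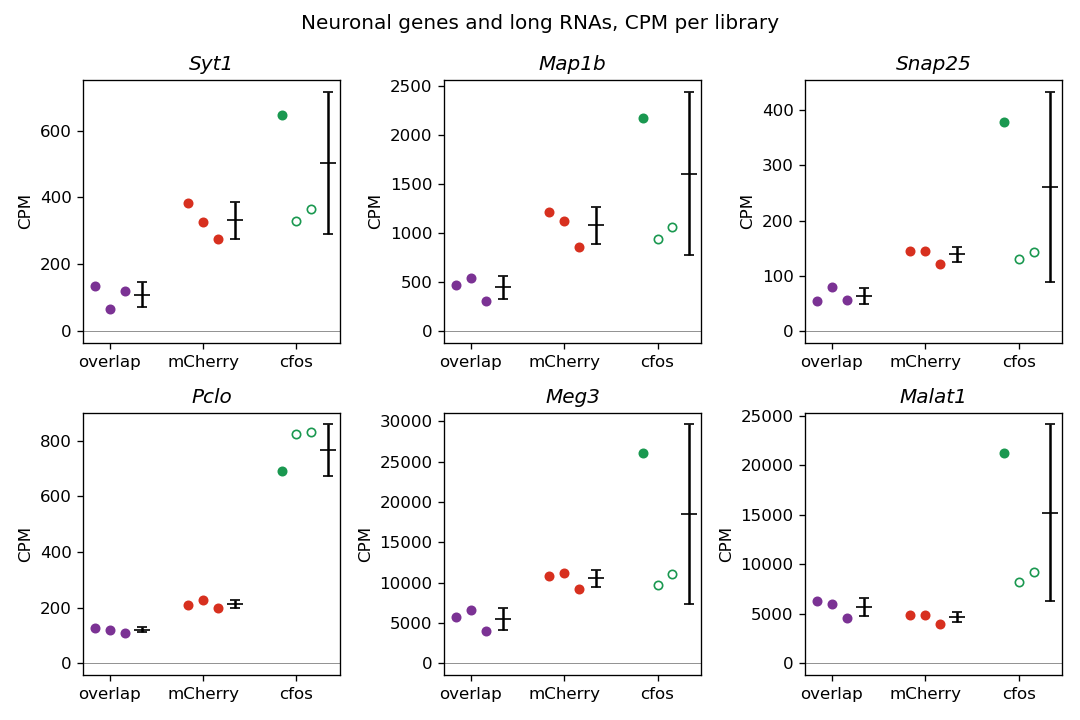
CPM (linear axis) of the neuronal genes Syt1, Map1b, Snap25 and Pclo and the long RNAs Meg3 and Malat1 in each library. Points are libraries (open points are cfos 2 and cfos 3, averaged as 1 replicate) and bars are the mean ± SD over 3 overlap, 3 mCherry and 2 cfos replicates; Pclo lies between 110 and 129 CPM in the overlap libraries and between 693 and 833 CPM in the cfos libraries.

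Pclo (ENSMUSG00000061601, chromosome 5, 14514918 to 14863459, protein-coding) stood at 121 ± 9.35 CPM in overlap (SD, n = 3) and at 766 ± 92.1 CPM in cfos (SD, n = 2). Its log2 fold change was -2.66 (SE 0.35, adjusted p = 0.128 over all genes, with a range of 6.8e-15 to 0.681 over the alternatives). Syt1 had -2.22 (SE 0.46), Snap25 -2.03 (SE 0.58), Map1b -1.85 (SE 0.38), Nefl -1.95 (SE 0.50), Map2 -1.84 (SE 0.48) and Syngr1 -2.39 (SE 0.73). Adjusted over the list alone, 6 pan-neuronal and 2 vesicle genes passed, all lower in overlap, and 0 over all genes. Of the ion channel and receptor lists, sodium, calcium and HCN channels had 23 of 27 members below 0 (median -0.60), potassium channels 18 of 28 (-0.38) and glutamate receptors 18 of 22 (-0.50), with 0 members past the threshold in each. Scn2a, a sodium channel gene, had a log2 fold change of -1.29 (SE 0.33), the AMPA receptor genes Gria1 and Gria2 -2.13 (SE 0.69) and -1.05 (SE 0.34), and the calcium-activated potassium channel gene Kcnma1 -1.17 (SE 0.48). Hcn4 at 3.53 (SE 2.13) and the kainate receptor gene Grik1 at 1.36 (SE 0.65) pointed the other way. The postsynaptic scaffold and calcium signalling list had 19 of 26 members below 0 (median -0.80), among them Nrxn2 (-1.39, SE 0.37) and Camk2b (-1.23, SE 0.37).

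For oxidative phosphorylation, Ndufa2 and Ndufa4 of complex I had log2 fold changes of -4.09 (SE 1.14) and -3.05 (SE 1.02), and 0 of 50 members passed. The higher values were those of cfos 1: Ndufa2 stood at 208 CPM there and at 24.4 and 29.8 CPM in cfos 2 and cfos 3 (overlap mean 6.84), Ndufa4 at 128 CPM against 35.4 and 44.8 (10.2), and Snap25 at 378 CPM against 131 and 144 (63.7). Cytosolic ribosomal protein genes had 52 of 69 members below 0 and a median of -0.48, with Rpl19 at -3.09 (SE 0.93), Rps9 at -4.07 (SE 1.48) and Rpl29 at 5.48 (SE 1.55) the other way; reads of these genes can be shared with their many pseudogenes. Among the long RNAs, Meg3 had -1.75 (SE 0.36), Malat1 -1.42 (SE 0.33) and Snhg11 -1.49 (SE 0.40), and these 3 passed adjusted over the list alone. They too were highest in cfos 1. Meg3 stood at 26030 CPM there and at 9714 and 11080 CPM in cfos 2 and cfos 3 (overlap mean 5511). Malat1 was at 21240 CPM against 8259 and 9267 (5671), and Snhg11 at 2222 CPM against 1122 and 1236 (615). Of the glial lists, 2 oligodendrocyte and 2 astrocyte members passed adjusted over the list alone, and 0 over all genes. Among them were Mal, which had 1 count in overlap and a cfos to overlap ratio of 48 (95% counting interval 8.4 to 1916), and Apoe (-4.17, SE 1.06). Apoe stood at 2803 CPM in cfos 1 and at 124 and 152 CPM in cfos 2 and cfos 3. The share of counts in olfactory and vomeronasal receptor genes, which brain neurons are not known to express at high levels, was 1.97%, 1.89% and 1.87% in overlap and 0.923%, 1.59% and 1.55% in cfos, and thus differed in the direction opposite to these lists.

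By camera the adjusted p was 1.01e-08 for vesicle release, 4.4e-08 for pan-neuronal genes, 6.7e-05 for oxidative phosphorylation, 0.000284 for the long RNAs, 0.000998 for the postsynaptic list, 0.00138 for ribosomal proteins, 0.00214 for oligodendrocyte markers, 0.00253 for sodium, calcium and HCN channels, 0.00889 for astrocyte markers, 0.0104 for potassium channels and 0.0147 for glutamate receptors. With an estimated correlation the adjusted p = 0.097 for the vesicle, postsynaptic and ribosomal lists, the smallest of the 11. By fry, 6 lists passed. The number of lists was 11 without mCherry 2, 10 with all 9 columns and 10 to 12 when any 1 library was left out. Astrocyte markers did not pass without overlap 1 (adjusted p = 0.0561), glutamate receptors without overlap 3 (0.0598), sodium, calcium and HCN channels without cfos 1 (0.0708), and potassium channels without overlap 1 (0.0554), mCherry 3 (0.055) or cfos 1 (0.117). The oxidative phosphorylation median was -0.32 without cfos 1. With a stricter count filter 8 lists passed, not all of them among the 11. Oligodendrocyte markers had too few members left for a test there. Under that filter oxidative phosphorylation (median -0.45, adjusted p = 0.207), ribosomal proteins (0.0639), glutamate receptors (0.167) and potassium channels (0.205) did not. With neither cfos 2 nor cfos 3, astrocyte markers (median -0.16, adjusted p = 0.0724) and glutamate receptors (0.118) did not. The other 17 lists had adjusted p between 0.0887 and 0.943.

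edgeR called 0 of 16410 single genes, with 1942 at an unadjusted p under 0.05, while DESeq2 called 893, limma-voom with sample weights 0 and edgeR without a count filter 214. Without mCherry 2, edgeR called 0 (1272 at an unadjusted p under 0.05 of 15274), DESeq2 412, limma-voom 0 and edgeR without a filter 42, and with all 9 columns edgeR called 15, 13 higher and 2 lower in overlap. None of the genes with the smallest p passed. Ermap (ENSMUSG00000028644, chromosome 4, 119175457 to 119190011, protein-coding), an erythroid membrane protein gene, had 0 counts in every cfos library and was at least 141-fold higher in overlap (adjusted p = 0.128). Smpdl3b, Gramd2 and Scarf1 also had 0 counts in cfos and were at least 98.8-fold, 45.2-fold and 68.5-fold higher, against a floor of 3 counts over the group, and Prss43 had a log2 fold change of 3.59 (SE 0.64). On the lower side stood Pclo, Meg3, Syt1, Map1b and Ntm, the last at -2.47 (SE 0.35, adjusted p = 0.147). Of the PVH peptide genes, Crh had a log2 fold change of 2.27 (SE 1.64), Sst -3.33 (SE 1.87), Trh -0.20 (SE 1.17), Oxt -0.13 (SE 0.97) and Avp 1.44 (SE 1.36), which became -0.01 without overlap 2. Fos had 0.28 (SE 0.99), Slc17a6 -0.59 (SE 0.86) and Gad2 -1.21 (SE 0.91), and all of these had adjusted p of 0.513 or more.

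**Figure D3:**
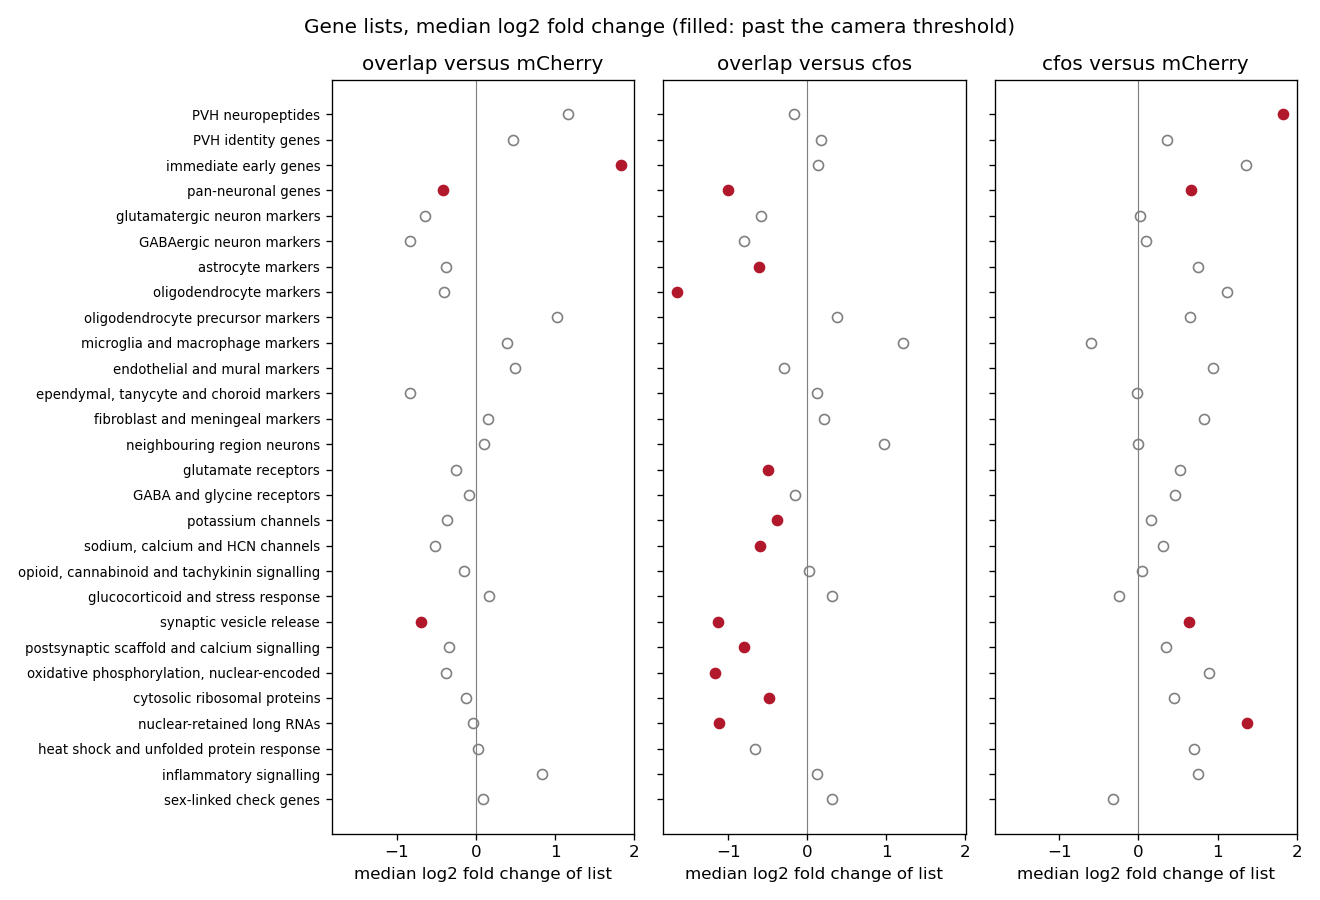
Median log2 fold change (horizontal axis) of each of the 28 tested gene lists in the 3 comparisons, with 1 point per list. Filled points passed the camera test with its preset correlation: 3 lists in overlap versus mCherry, 11 in overlap versus cfos, all below 0, and 4 in cfos versus mCherry, all above 0; none passed with an estimated correlation.

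The cfos and mCherry groups were compared to ask how the cells of each single label differed. PVH neuropeptide and granule genes were higher as a group in cfos, with 11 of 12 members above 0 and a median log2 fold change of 1.83. Pan-neuronal genes (median 0.67, 21 of 24 members above 0), synaptic vesicle genes (0.64, 26 of 32) and nuclear-retained long RNAs (1.37, 8 of 9) were higher as groups too. None of the 4 calls held with an estimated correlation (adjusted p = 0.516 to 0.589), and without cfos 1 the medians were 1.48, 0.24, 0.18 and 0.94 in this order, with none past the threshold. The granule protein genes Scg2 and Vgf stood at 808 ± 555 and 106 ± 80.7 CPM in cfos (SD, n = 2) and at 160 ± 22.4 and 14.9 ± 3.46 CPM in mCherry (SD, n = 3).

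Scg2 (secretogranin II) had a log2 fold change of 2.33 (SE 0.51) and Vgf 2.81 (SE 0.89). The higher values were those of cfos 1. Scg2 stood at 1186 CPM there and at 373 and 437 CPM in cfos 2 and cfos 3, and Vgf at 161 CPM against 39.0 and 53.3. Avp had 68 counts in cfos, with cfos 2 and cfos 3 averaged, and 3 in mCherry, a ratio of 20.5 (95% counting interval 6.71 to 102). Chgb (chromogranin B) had a log2 fold change of 1.85 (SE 0.85). Adjusted over the list alone, Scg2, Vgf and Avp passed, and over all genes 0 did. Among the pan-neuronal genes, Snhg11 (1.46, SE 0.40) and Map2 (1.52, SE 0.48) lay above 0 and Elavl2 below (-1.14, SE 0.58), and among the vesicle genes Pclo (1.84, SE 0.34), Syn2 (1.98, SE 0.69), Sv2a (0.97, SE 0.42) and Synj1 (1.58, SE 0.70) lay above 0, of which only Pclo passed adjusted over the list alone. Of the long RNAs, Malat1 had 1.70 (SE 0.33) and passed adjusted over the list alone, as did Snhg11, while Meg3 had 0.81 (SE 0.35), which became 0.016 without cfos 1. Malat1 was at 21240 CPM in cfos 1 and at 8259 and 9267 CPM in cfos 2 and cfos 3, against 4011 to 4917 CPM in mCherry. The share of counts in olfactory and vomeronasal receptor genes was 1.86%, 1.89% and 1.99% in mCherry, above all cfos libraries.

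By camera the adjusted p was 0.00437 for neuropeptides, 0.0367 for the long RNAs and 0.0389 for both pan-neuronal and vesicle genes. With an estimated correlation the adjusted p = 0.516 for neuropeptides and long RNAs and 0.589 for the other lists called. Glial markers lay above 0 as well and did not pass: oligodendrocyte markers with a median of 1.12 and 9 of 11 members above 0 (0.15), and astrocyte markers with 0.76 and 12 of 16 (0.206). Without mCherry 2, without mCherry 1 or without mCherry 3, 1 list passed, without cfos 3 2 lists, without cfos 1 0, and with all 9 columns 1. Without mCherry 2 and with all 9 columns this list was the neuropeptides (adjusted p = 0.0118 and 0.0129). Among the omissions, the neuropeptide list failed only without cfos 1. In that omission the long RNAs, the pan-neuronal list and the vesicle list failed as well. These last 3 lists also failed without mCherry 1 (0.0603, 0.0603 and 0.0878), mCherry 2 (0.147, 0.233 and 0.233) and mCherry 3 (0.0611 each), and the pan-neuronal and vesicle lists without cfos 3 (0.0609 each). The other 24 lists, immediate early genes among them (median 1.36, adjusted p = 0.0678), had adjusted p between 0.0678 and 0.968.

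edgeR called 0 of 16410 single genes, with 2899 at an unadjusted p under 0.05, while DESeq2 called 1530, limma-voom with sample weights 2163 and edgeR without a count filter 1197. Without mCherry 2, edgeR called 0 (1422 at an unadjusted p under 0.05 of 15274), DESeq2 553, limma-voom 0 and edgeR without a filter 130. With all 9 columns as deposited, edgeR called 247 genes, 92 higher and 155 lower in cfos. The smallest adjusted p, 0.0626, belonged to Ermap, which had 453 counts in mCherry, 0 in cfos, and was at least 167-fold lower in cfos. Smpdl3b, Gramd2 and Scarf1 were at 0 in cfos as well, at least 148-fold, 120-fold and 118-fold lower, and Tmeff2 had a log2 fold change of -3.89 (SE 0.66). Dapk2 and Armh3, at 0 in mCherry, were at least 173-fold and 108-fold higher in cfos, Rmdn1 had a ratio of 445 (95% counting interval 123 to 3682), and Gnaz, a G protein alpha subunit gene, had a log2 fold change of 2.76 (SE 0.49). Of the fixed genes, Crh had 2.32 (SE 1.56), turning to -0.15 without cfos 1, Sst 3.75 (SE 1.86), Gad2 2.08 (SE 0.92), Trh 1.80 (SE 1.17), Oxt 0.86 (SE 0.96), Slc17a6 -0.05 (SE 0.86) and Fos 2.86 (SE 1.00), with adjusted p between 0.252 and 0.997. Slc32a1 had 17, 21 and 43 counts in the cfos libraries.

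Tested over the 3 groups together, edgeR called 0 of 16410 genes (smallest adjusted p = 0.196), DESeq2's likelihood ratio test 1236, limma-voom with sample weights 1210 and edgeR without a count filter 2031. Without mCherry 2 the counts were 0, 252, 0 and 219, and with all 9 columns edgeR called 3.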

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

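The settings with all 9 columns, with neither cfos 2 nor cfos 3, with mCherry 2 left out in DESeq2, limma-voom or without a filter, and without Fos in its list were chosen after the data were seen. Counts below are in the order overlap versus mCherry, overlap versus cfos, cfos versus mCherry and the 3 groups together, where edgeR called 0, 0, 0 and 0 genes. DESeq2 called 905, 893, 1530 and 1236 genes, limma-voom 1332, 0, 2163 and 1210, and edgeR without a filter 484, 214, 1197 and 2031. With mCherry 2 left out, DESeq2 called 141, 412, 553 and 252, limma-voom 0 in each, and edgeR without a filter 13, 42, 130 and 219. All 9 columns gave 0, 15, 247 and 3. For cfos versus mCherry, upper-quartile scaling and the stricter filter gave 2 genes each. Leaving out any 1 library, removing mitochondrial and ribosomal protein genes, and fitting only the groups compared gave 0 genes in every comparison. The cause of the differences between tools was not tested.

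Of the 3, 11 and 4 called lists, an estimated correlation kept 0, 0 and 0, and fry kept 0, 6 and 1. For cfos versus mCherry fry also passed the postsynaptic and ribosomal lists, which camera did not call (adjusted p = 0.0423 each). For overlap versus mCherry, 5 lists were called without a filter, 6 without a filter and mCherry 2, 5 by limma-voom without mCherry 2 and 7 with neither cfos 2 nor cfos 3. For cfos versus mCherry, RLE scaling gave 1, all 9 columns 1, limma-voom without mCherry 2 0, no filter without mCherry 2 1, and neither cfos 2 nor cfos 3 7. Leaving out 1 library gave 0 to 3, 10 to 12 and 0 to 6 lists. The causes were not tested. Without cfos 1, or with neither cfos 2 nor cfos 3, the lone cfos replicate is assumed to vary like the other groups. The medians of all called lists kept their sign under every alternative, while for overlap versus cfos they ranged from -1.35 to -0.32 for oxidative phosphorylation and from -1.34 to -0.16 for astrocyte markers. RLE scaling moved the median of all genes by -0.112 in overlap versus mCherry and by -0.178 in cfos versus mCherry, and by 0.067 in overlap versus cfos.

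Signs of named genes, none past the threshold, turned as follows (log2). Limma-voom gave Meg3 -0.030 and Slc17a6 0.25 for cfos versus mCherry, and Oxt -0.21 and Sst -0.42 for overlap versus mCherry. Upper-quartile scaling gave Fos -0.017 for overlap versus cfos and Slc17a6 0.051 for cfos versus mCherry. Neither cfos 2 nor cfos 3 gave Fos -0.45, Oxt 0.070, Aspa 0.16 and Trh 0.55 for overlap versus cfos. With 1 library left out, overlap versus mCherry ranged from -1.25 to 1.25 for Oxt and from -3.92 to 0.99 for Sst. Overlap versus cfos ranged from -0.010 to 2.11 for Avp, -0.12 to 2.88 for Fos, -2.12 to 0.38 for Oxt and -0.67 to 0.19 for Trh. For cfos versus mCherry the ranges were -0.15 to 4.45 for Crh and -0.45 to 0.39 for Slc17a6. The causes were not tested.

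The replicate numbers showed no pairing of the samples, which the comparison could hardly detect. The columns cfos 2 and cfos 3 count as 1 replicate and mCherry 2 was nested, so pairing is not excluded. Same-numbered libraries of different groups had correlations of deviations from -0.0587 to 0.0553, and 3 of 9 columns correlated best with their own number. The replicate block called 0, 0, 0 and 0 genes and 3, 12 and 6 lists, and with all 9 columns, 0, 0, 0 and 0 genes and 2, 10 and 1 lists. For overlap versus mCherry the block gave Oxt -0.13 and Sst -0.21, and Sst -0.023 with all 9 columns. Depth limits genes of low abundance: in overlap, 3 counts are 5.02 to 5.94 CPM.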

Other observations

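The tests of nested columns, of background reads, of genes at 0 in cfos 1 and of left-out mCherry libraries were chosen after the patterns they bear on had been seen, and the tests of the narrowed spread, the matched lists, the wrong label by immediate early genes and the splits of the samples were fixed before their results. The limits for left-out mCherry libraries were set, and the unadjusted counts of the splits and the immediate early share were added, after their values had been seen. Genes in the next paragraph lie outside the naming rule and were chosen after their values were seen, most because they passed adjusted over their list alone; Ddx3y did not and is set beside Xist.

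Oligodendrocyte precursor markers had 6 of 7 members above 0 in overlap versus mCherry, with a median log2 fold change of 1.03 (camera adjusted p = 0.218). The proteoglycan genes Cspg4 (4.10, SE 1.11) and Cspg5 (1.44, SE 0.44) passed adjusted over the list alone and not over all genes (adjusted p = 0.258 and 0.26). Tac2, the gene of neurokinin B, was lower in overlap than in cfos (-4.80, SE 1.30, adjusted p = 0.0386 over the list alone and 0.354 over all genes), and the transcription factor gene Neurod2 was higher in cfos than in mCherry (3.78, SE 1.07, adjusted p = 0.0381 and 0.224). Xist, the RNA of the inactive X chromosome, had 26, 7 and 1 counts in overlap, 114, 8 and 10 in mCherry and 0 in each cfos column, while the Y-linked gene Ddx3y had counts in all 9 columns, from 8 to 76. Against mCherry, Xist (adjusted p = 0.0494 over the list alone and 0.236 over all genes) was lower in cfos, as was the ependymal gene Ccdc153 (0.02 and 0.222), at 356, 36.2 and 63.7 CPM in mCherry and 0 in each cfos column. Microglia and macrophage markers had 9 of 10 members above 0 in overlap versus cfos (median 1.21, camera adjusted p = 0.199).

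The median log2 CPM of 20 immediate early genes other than Fos was 5.67, 5.39 and 4.72 in the overlap libraries, 4.52, 4.47 and 3.50 in the mCherry libraries, 5.60 in cfos 1 and 4.68 in the mean of cfos 2 and cfos 3. Btg2, for which 93.7 to 147 CPM in overlap stood against 7.32 to 34.6 CPM in all other libraries, did not pass over all genes against mCherry (adjusted p = 0.259, with a range of 0.00617 to 0.864 over the alternatives).

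Nested columns are the first pattern. In cfos 2, 0 of 54838 genes had a higher count than in cfos 3, against 1199 to 1353 genes in 100 simulations of independent Poisson libraries of the same depths, and mCherry 2 exceeded the sum of mCherry 1 and mCherry 3 in 0 genes, against 910 to 1057 simulated. Independent libraries that differ by sampling noise, or an independent mCherry 2 of intermediate expression, are therefore excluded, and a candidate explanation is that reads of cfos 2 are part of those of cfos 3, and reads of mCherry 2 part of those of mCherry 1 and mCherry 3. Of 548 genes with at least 40 counts in mCherry 3 and 0 in mCherry 1, all were detected in mCherry 2, at a median ratio of 0.529, while of 635 genes with at least 40 in mCherry 1 and 0 in mCherry 3, 100 were not. Whether reads counted in more than 1 column narrow the spread enough to give the 247 genes of cfos versus mCherry was put to simulation. With no group difference, and mCherry 2 drawn as fixed shares of mCherry 1 and mCherry 3, the median was 0 called genes (highest 8). The share at an unadjusted p under 0.05 was 17.6%. The real mCherry 2 is not such a draw, since 100 of the 635 genes above were not detected in it. Simulations without group differences also cannot show how far shared reads push modest differences past the threshold, so the question stays undecided. No biological explanation was tested, and real differences between the groups stay open for those genes.

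Lower neuronal and metabolic lists in overlap are the second pattern. In overlap versus cfos, 8 of the 11 called lists had medians below the lower 2.5% of 10000 random lists matched on abundance. The lists had already been called on the same fold changes, and the random lists draw genes independently. The number of lists is therefore no separate support for the calls. For those 8 lists the typical matched median lay between -0.0396 and 0.125, which argues against a shift common to genes of the same abundance. Astrocyte markers, glutamate receptors and potassium channels had typical matched medians above 0 too (0.0544, 0.0709 and 0.122), which argues against such a shift there. Their own medians lay within the matched range, so random lists of the same abundance reach such medians. The pan-neuronal list of overlap versus mCherry lay within its matched range as well (median -0.42, matched range -0.488 to 0.347). Its typical matched median was -0.1, so a shift of genes of that abundance may account for part of it. More background reads in the overlap libraries may contribute in overlap versus cfos. There the lowest overlap share of counts in olfactory and vomeronasal receptor genes lay 0.278 percentage points above the highest cfos share. The lowest mCherry share (1.86%) also lay above the highest cfos share (1.59%), so background may contribute to the lists of cfos versus mCherry too. In overlap versus mCherry the shares overlapped (lowest overlap minus highest mCherry, -0.127 points), so that background as measured by these genes is argued against for the lists called there. A difference between the kinds of labelled cells, which the groups name, stays open and untested, as does the number of cells captured per library.

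Low Fos in the libraries labelled cfos 2 and cfos 3 is the third pattern; a wrong label, with cells of the mCherry kind, would put their other immediate early genes at or below the mCherry libraries, and the median of cfos 2 and cfos 3 lay 0.158 log2 units above the highest mCherry library (SD 0.576 among these), while the share of counts in this list with Fos was 0.0515% and 0.0566%, below every mCherry library (0.0818% to 0.0978%), as were Egr1, Junb and Btg2. Of the 10 genes named by smallest p in overlap versus mCherry, 9 lay outside all mCherry libraries on the overlap side in both columns. The cfos replicates entered the estimated spread behind those p-values, which can favour genes on which they agree. How far this shaped the choice was not measured, so these 9 genes do not settle the label. Of the 7 genes fixed in advance other than Fos that passed the count filter, 5 (Avp, Gad2, Oxt, Sst and Trh) were above every mCherry library in both columns. Avp and Sst had at most 3 counts in an mCherry library. Crh and Slc17a6 were not above, nor was Slc32a1, below the filter (12.6 CPM in cfos 2 and 13.1 CPM in mCherry 1). The columns are 1 replicate and the share over all genes was not measured, so these fixed genes do not settle the label. Those 10 genes were picked with all mCherry libraries, and when genes were picked with 1 of them, the share nearer to it than to overlap was higher in the left-out mCherry library than in cfos 2 and cfos 3 in 17 of 18 versions tried (by -0.905 to 5.83 points), but cfos 1 was nearer than the left-out library in 11. Of the 927 genes with at least 40 counts in mCherry 1 and 0 in cfos 1, 38.5% were at 0 in cfos 3 and 38.8% in mCherry 3. Starting from mCherry 3, with 980 genes, 37.9% were at 0 in cfos 3 and 34.7% in mCherry 1, a difference of 3.16 points. The overlap libraries had 22% to 42.3% and 18.5% to 38.7% at 0, so cfos 3 was not below all of them. The shallower cfos 2 had 394 and 402 of these genes at 0. The mean of cfos 2 and cfos 3 correlated more with cfos 1 and the overlap libraries (0.504 to 0.515) than with mCherry 1 and mCherry 3 (0.43 to 0.433), but mCherry 1 and mCherry 3 also correlated less with each other (0.365) than with those libraries (0.38 to 0.441), so that a wrong label and a cfos library with weak induction cannot be told apart with so few libraries.

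For overlap versus mCherry, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Every split gave 0 genes, the real one included, which decides nothing about single genes. At an unadjusted p under 0.05 the real split had 2457 genes and the other 9 had 168 to 917, but without any group difference the nested mCherry 2 raised the share under 0.05 to 10.9% in simulations. The real split gave 3 lists and the highest of the others 5, with 2 splits as large, the real one included.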
